A study of Homo sapiens with 8 samples.

How the data were processed

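The series measured messenger RNA in Raji cells, an established human Burkitt lymphoma B-cell line, on 8 two-colour Agilent oligonucleotide arrays. Per the labels' protocols, cells received 10 uM PP2 or 100 nM dasatinib for 24 h, and vehicle-treated cells were the control. Per the labels, total RNA was isolated with a column kit, and amplified and dye-labelled as complementary RNA with Agilent's Quick Amp kit. Each array held treated RNA in one dye and control RNA in the other. There were 4 PP2 and 4 dasatinib arrays. Replicates 1 and 2 of each compound carried the treated RNA in Cy5 (red), and replicates 3 and 4 were dye swaps with the treated RNA in Cy3 (green), as the labels of each channel give them. The labels number the controls separately on every array and name some arrays biological replicates and others dye swaps. They do not say whether a swap reused the RNA of an earlier array, or whether the compounds shared control extracts. The p-values therefore measure the spread between these arrays, which may be technical.

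The deposited scanner files held spot intensity on a linear scale, the mean signal and the median local background of each channel, per the file headers. They were made with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes and 10.10.1.1 per the file headers, with probe coordinates on hg19 per the file headers. The same deposited files held a log10 ratio of red over green, which Feature Extraction had background-subtracted and dye-normalized, per the file headers. The authors' deposited value table was also on a log10 scale. It was set against the scanner files spot by spot. It equalled their log10 ratio on the arrays with treated RNA in Cy5 (r = 1) and its negative on the dye swaps (r = -1), with a largest difference of 4.97e-06. Its direction was therefore treated over control on all 8 arrays, its median was 0 on each, and no part of its scale, centring or direction stayed unknown. All 8 arrays lay on 1 slide with 1 scan, so neither could be tested as a batch. No spot was saturated. Spots well above background made up 58.5% to 62.6% of the green and 57.9% to 64.7% of the red spots per array, and 498 to 692 spots per array carried an outlier mark. For these arrays, their number limits the precision.

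From the intensities, background was corrected by normexp with an offset of 50, and red over green log2 ratios were normalized by loess within each array, with control spots and outlier-marked spots at weight 0. Control spots (4259 of 62976) and outlier-marked spots were then left out. Spots of the same probe were averaged. The 58717 remaining spots held 50599 probes. Gene names came from the files. Of the probes, 28170 were matched to a current symbol through their accession, 2621 through the symbol itself and 620 through a synonym, using a table of RefSeq genes given for names only. The other 19188 kept the file's name, and 5006 probes took a name that differs from the array design's. No genome sequence or hg19 annotation was used, so a probe's exon or untranslated region is not given.

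A probe was kept when it was well above background on every channel of at least 1 RNA group, meaning 4 PP2, 4 dasatinib or 8 control channels. This kept 28878 probes. Each gene was represented by its kept probe with the highest mean log2 signal, which gave 21998 genes. Of the genes named by the rule below, 47 of 166 had over 1 kept probe, and in 0 of them did probes pass the threshold in opposite directions. The probe used passed and another kept probe did not for 7 of the 28 genes with over 1 kept probe that were named for PP2, 9 of 29 for dasatinib and 1 of 5 for the difference. Probes of a gene that pass in the same direction can still differ in size. Where a probe was well above background on no channel of the treated or control RNA of a compound's arrays and on every channel of the other, the fold is given as a bound, "at least". It is the bright group's mean against, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal, per channel after loess and Aquantile scaling between arrays.

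Ratios were fitted with limma (lmFit and eBayes) in a single model over all 8 arrays, with a PP2 term and a dasatinib term signed by dye, and a probe-specific dye term, leaving 5 residual degrees of freedom. Both compounds thus shared the estimate of the spread. The contrast PP2 minus dasatinib tested the difference between the effects. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all tests were two-sided. Values are log2 fold changes of treated over control. A value after ± is the standard error of the fit, which rests on 4 arrays per compound, unless SD is named.

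The comparisons, their settings, the rule for named genes, 28 gene lists and all alternatives except the crossed replicate block were fixed before the data were examined. The lists were B cell surface and co-receptor genes, SRC family kinases and their regulators, B cell receptor signalling, B cell transcription factors, plasma cell genes, ERK pathway feedback and target genes, immediate early genes, NF-kappaB target genes, G1/S and DNA replication genes, G2/M genes, MYC target and ribosome biogenesis genes, BCL2 family genes, p53 target genes, ATF4 and amino acid response genes, unfolded protein response genes, cholesterol synthesis and uptake genes, glycolysis and hypoxia genes, interferon-stimulated genes, MHC class II genes, FOXO target genes, chemokine receptors and adhesion genes, complement regulators, AHR target genes, NRF2 target genes, lysosome genes, heat shock genes, and as markers of other cells those of T, NK and myeloid cells and those of fibroblasts and epithelial cells. Some genes stand in more than 1 list. Lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. The list test of the difference between compounds was added later. Genes with a missing value on some array (45) were left out of list tests.

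The named genes were MS4A1, the SRC family kinases, and for each compound the 8 highest and 8 lowest genes past the threshold with a symbol, the same direction on all 4 arrays and both channels well above background on all 4. To these came up to 4 members past the threshold, by size of change, of each list that was shifted or held at least 3 such members, and up to 4 genes with the largest bound. For the difference, the 6 highest and 6 lowest were taken under the same filter on all 8 arrays. Genes named outside this rule are said to be chosen after their values were seen.

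The alternatives were no background correction, a normexp offset of 16, Agilent's log ratio, median centring in place of loess, scale normalization between arrays, the deposited value table, no filter on dim probes, probes well above background on all 16 channels, saturated probes left out, every probe as its own feature, the median of a gene's probes, no dye term, each compound fitted alone, eBayes with trend and robust settings, dye swaps averaged as technical replicates in label order and in the other pairing, a replicate block, each array left out in turn, and a threshold that also required a 2-fold change.

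The fit was tested on simulated data in which 100 genes per size were changed. At a log2 size of 0.5 it recovered 89% of the genes for PP2, 93% for dasatinib and 72% for the difference. At a size of 1 it recovered 100%, 100% and 98%. It made 10, 7 and 12 false calls among 21953 genes. A simulated shift of -0.3 in the NF-kappaB list with PP2 was found, and 0 of 26 other lists were called. The simulated noise was independent between genes, so it cannot show how often camera calls unshifted lists whose genes are correlated. R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and Python 3.11.15 with pandas 2.3.3, matplotlib 3.10.9 and scipy 1.17.1, were used.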

Results

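Transcript levels were compared between Raji cells exposed for 24 h to an inhibitor of SRC family kinases and vehicle-treated Raji cells. SRC family kinases are tyrosine kinases that start signalling from the B cell receptor. PP2 was used at 10 uM and dasatinib at 100 nM, so the doses differ. Each compound was measured on 4 two-colour arrays, 2 of each dye orientation, and 21998 genes were tested. Across genes, log2 ratios of arrays with the same dye orientation correlated at 0.84 and 0.88 for PP2 and at 0.74 for dasatinib. Arrays of opposite orientation correlated at 0.39 to 0.50 for PP2 and at 0.32 to 0.44 for dasatinib, and the fit carries a dye term for each probe. The residual SD between arrays had a median over genes of 0.094 for PP2 and 0.091 for dasatinib on the log2 scale.

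The series asks how SRC family kinases bear on CD20, the B-cell surface protein encoded by MS4A1 and bound by therapeutic antibodies such as rituximab. MS4A1 transcripts were 8.58-fold lower with PP2 and 4.18-fold lower with dasatinib. The log2 changes were -3.10 ± 0.085 with PP2 (limma adjusted p = 1.5e-10) and -2.06 ± 0.085 with dasatinib (adjusted p = 1.1e-08). MS4A1 was lower on all 8 arrays, with an SD between arrays of 0.32 for PP2 and 0.14 for dasatinib (n = 4 each). The difference, PP2 minus dasatinib, was -1.04 (95% CI -1.30 to -0.78, adjusted p = 2.2e-04). The array holds 1 probe for MS4A1, on chromosome 11 at 60238115 to 60238174 (hg19).

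Transcripts of the kinases themselves moved in different directions. With PP2, FGR (-1.61 ± 0.042) and LCK (-1.39 ± 0.049) fell, and FYN (0.47 ± 0.066) and LYN (0.29 ± 0.053), the main SRC family kinase of B cells, rose. With dasatinib, FGR (-0.58 ± 0.042) and LCK (-0.47 ± 0.049) fell by less, with differences of -1.03 ± 0.059 and -0.91 ± 0.070 that passed the threshold. FYN (0.25 ± 0.066) and BLK (0.31 ± 0.059) rose with dasatinib, whereas LYN was at -0.078 ± 0.053 (adjusted p = 0.37). The FYN call with dasatinib was lost in 6 of the alternative settings, among them those without dasatinib replicate 1 (0.18, adjusted p = 0.12), replicate 2 (0.25, 0.091) or replicate 4 (0.23, 0.12). The BLK call with dasatinib was lost without the dye term (adjusted p = 0.092). LYN differed between the compounds (difference 0.37 ± 0.075, adjusted p = 0.0082). With median centring LYN was at 0.13 with dasatinib, and its difference was not called (0.27, adjusted p = 0.17). BLK was at 0.012 with PP2 (adjusted p = 0.90), and its difference of -0.29 (adjusted p = 0.044) was lost in 13 of 24 alternatives. SRC did not pass the threshold with PP2 (-0.10, adjusted p = 0.085) or dasatinib (-0.098, adjusted p = 0.15), but did with Agilent's log ratio (-0.19, adjusted p = 0.040, and -0.23, adjusted p = 0.041). The probes of YES1 and FRK were too dim to be tested.

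**Figure D1:**
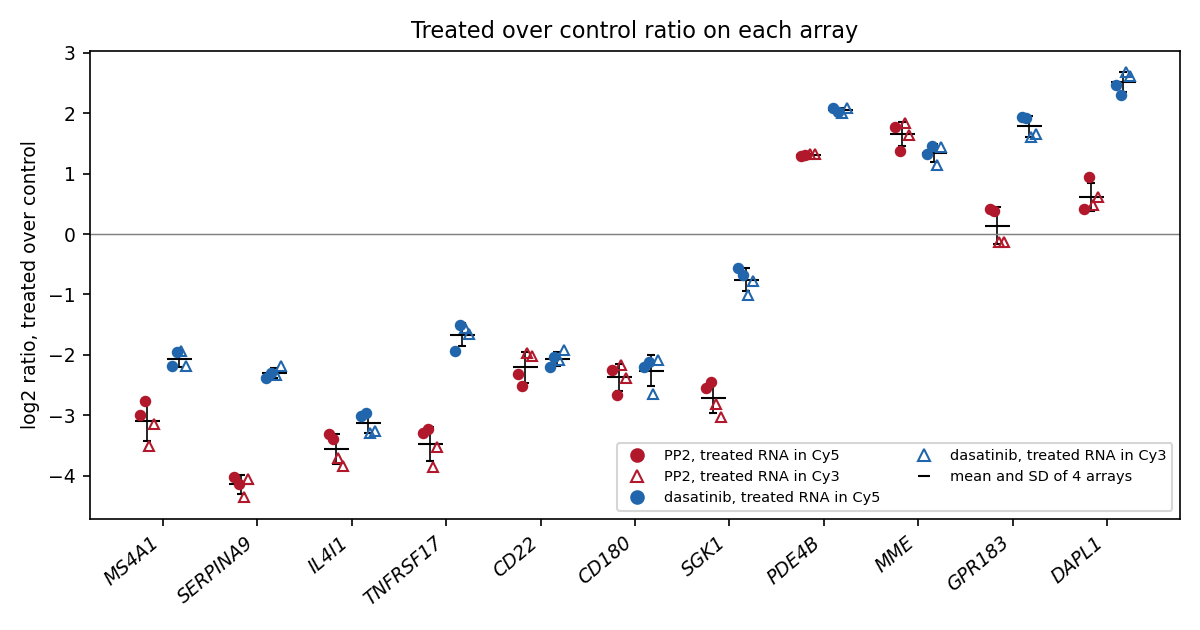
Log2 ratio of treated over control (vertical axis) on each array for 11 genes (horizontal axis), with PP2 in red and dasatinib in blue, filled circles for treated RNA in Cy5, open triangles for treated RNA in Cy3, and bars for the mean and SD of 4 arrays. MS4A1 lies at or below -1.94 on all 8 arrays, and DAPL1 lies highest with dasatinib.

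The largest changes with PP2 were falls. SERPINA9, a protease inhibitor of germinal-centre B cells, was 17.7-fold lower (-4.14 ± 0.059). IL4I1, a secreted amino acid oxidase, was 11.8-fold lower (-3.56 ± 0.046), and TNFRSF17, the receptor BCMA, 11.1-fold lower (-3.47 ± 0.090). The kinase gene SGK1 was 6.52-fold lower (-2.71 ± 0.056). C17orf99 was 6.37-fold lower (-2.67 ± 0.059) and RGS13, a regulator of G protein signalling, 6.31-fold (-2.66 ± 0.082). Increases were smaller. RNF186, a ubiquitin ligase, was 3.35-fold higher (1.74 ± 0.054), and MME, the surface peptidase CD10, 3.16-fold (1.66 ± 0.074). TXNIP, an inhibitor of thioredoxin and glucose uptake, was 2.86-fold higher (1.51 ± 0.082) and PDCD4, an inhibitor of translation, 2.72-fold (1.44 ± 0.045). TSPOAP1 was 2.71-fold higher (1.44 ± 0.052), the stress gene GADD45A 2.65-fold (1.41 ± 0.053) and the cyclic AMP phosphodiesterase PDE4B 2.48-fold (1.31 ± 0.042). The probe of the ribosomal RNA gene RNA18SN5, which has near-identical copies, read 1.65 ± 0.40 (adjusted p = 0.0065). Its call was lost without PP2 replicate 1 (1.33, adjusted p = 0.055) and with the trend and robust settings of eBayes (adjusted p = 0.087). The SERPINA9 probe lies on chromosome 14 at 94931144 to 94933457 (hg19). Each of these genes moved the same way on all 4 PP2 arrays, with a limma adjusted p of at most 5.7e-08 except for RNA18SN5. Among probes not well above background with PP2, HECW2 was at least 2.96-fold lower, HCAR3 at least 2.91-fold and LMO2, a germinal-centre transcription cofactor, at least 2.01-fold.

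In all, 7936 of 21998 genes (36.1%) passed the threshold with PP2, 4262 higher and 3674 lower, and 226 of them changed at least 2-fold, 46 higher and 180 lower. Higher genes were 53.7% of the calls, and 71.4% when arrays were median-centred in place of loess. Without the dye term the count was 4811. Of the 27 lists tested, 13 were shifted with PP2, 12 of them down, and 3 of these held with an estimated correlation, which were the NF-kappaB, unfolded protein response and cholesterol lists.

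In each of the B-cell lists, more genes fell than rose with PP2. Of 18 B cell surface and co-receptor genes, 8 fell, 5 rose and 5 did not pass the threshold (9 lower and 5 higher adjusted over the list alone). Next to MS4A1, falls were seen for CD180 (-2.37 ± 0.095), a Toll-like receptor homologue, CD22 (-2.21 ± 0.061), an inhibitory co-receptor, and FCRLA (-1.64 ± 0.053). The list's median was -0.20, with a camera adjusted p of 0.0077 and an adjusted p = 0.15 with an estimated correlation. Of 21 B cell receptor signalling genes, 12 fell, 5 rose and 4 did not pass the threshold (15 lower and 5 higher adjusted over the list alone). They included the guanine exchange factor gene RASGRP3 (-1.97 ± 0.047), the phosphatase gene PTPN6 (-1.53 ± 0.055) and the adaptor genes BLNK (-1.19 ± 0.049) and PIK3AP1 (-0.91 ± 0.10), all lower. Camera gave an adjusted p of 5.5e-04 at a median of -0.27, and adjusted p = 0.054 with an estimated correlation. Among 10 SRC family kinases and regulators, 5 fell, 2 rose and 3 did not pass the threshold (6 lower and 2 higher adjusted over the list alone). PAG1, an adaptor that recruits the inhibitory kinase CSK, fell by 0.74 on the log2 scale. Their median lay at -0.21 (camera adjusted p = 0.030, and adjusted p = 0.29 with an estimated correlation). This list's shift was lost without the dye term (adjusted p = 0.080) and without PP2 replicate 2 (0.057), over a range of 1.0e-04 to 0.080.

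Of 21 B cell transcription factor genes measured with PP2, 12 fell, 5 rose and 4 did not pass the threshold (13 lower and 5 higher adjusted over the list alone). Those that fell included BCL6 (-1.38 ± 0.053), the repressor that maintains germinal-centre cells, IRF8 (-0.97 ± 0.093) and MEF2B (-0.77 ± 0.059). At a median of -0.36, the camera adjusted p was 0.0024, or adjusted p = 0.087 with an estimated correlation. Of 14 plasma cell genes, 8 fell, 3 rose and 3 did not pass the threshold (8 lower and 3 higher adjusted over the list alone). JCHAIN (-1.90 ± 0.082), the joining chain of secreted antibody, and the chaperone gene HSP90B1 (-0.70 ± 0.043) fell after TNFRSF17, while CD38 (0.59 ± 0.045) rose. The list's median was -0.21, with a camera adjusted p of 0.015 and an adjusted p = 0.12 with an estimated correlation. MHC class II genes, which serve antigen presentation, were lower in 11 of 14, higher in 1 and under the threshold in 2 (12 lower and 2 higher adjusted over the list alone). The largest falls were those of HLA-DOB (-1.67 ± 0.059), HLA-DQB1 (-0.79 ± 0.052) and HLA-DQA1 (-0.72 ± 0.050), although probes of HLA genes can read near-identical copies. Camera gave an adjusted p of 1.6e-06 at a median of -0.46, and adjusted p = 0.12 with an estimated correlation.

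Most NF-kappaB target genes fell with PP2. Of 21 measured, 17 fell, 2 rose and 2 did not pass the threshold (17 lower and 3 higher adjusted over the list alone), with a median of -0.75 (camera adjusted p = 1.1e-11, and adjusted p = 0.040 with an estimated correlation). EBI3, a cytokine subunit gene, fell by 2.49 ± 0.050 on the log2 scale, and TRAF1 was 4.04-fold lower (-2.01 ± 0.069). RELB, a subunit of NF-kappaB itself, was 3.18-fold lower (-1.67 ± 0.046) and TNFAIP3, its feedback inhibitor, 2.87-fold (-1.52 ± 0.049). Of 19 chemokine receptors and adhesion genes, 11 fell, 4 rose and 4 did not pass the threshold (11 lower and 4 higher adjusted over the list alone). ICAM2 (-1.16 ± 0.055), ICAM1 (-1.15 ± 0.067), ITGB7 (-0.99 ± 0.053) and CD48 (-0.95 ± 0.049) were the largest falls. Their median lay at -0.40 (camera adjusted p = 7.7e-04, and adjusted p = 0.087 with an estimated correlation). Of 20 immediate early genes, 7 fell, 5 rose and 8 did not pass the threshold (8 lower and 6 higher adjusted over the list alone). The chemokine genes CCL3 (-1.75 ± 0.053) and CCL4 (-1.30 ± 0.056) fell and BTG2 (1.00 ± 0.054), an antiproliferative gene, rose (median -0.061, camera adjusted p = 0.25). Of 12 ERK feedback and target genes, 4 fell, 0 rose and 8 did not pass the threshold (4 lower and 0 higher adjusted over the list alone). Those that fell included SPRED2 (-0.74 ± 0.10), DUSP5 (-0.68 ± 0.043) and SPRED1 (-0.63 ± 0.050), all inhibitors of that pathway (median -0.035, camera adjusted p = 0.087).

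Most unfolded protein response and cholesterol genes were lower with PP2. Of 16 unfolded protein response genes, 13 fell, 0 rose and 3 did not pass the threshold (13 lower and 1 higher adjusted over the list alone), at a median of -0.60 (camera adjusted p = 3.7e-09, and adjusted p = 0.015 with an estimated correlation). The endoplasmic reticulum chaperone gene HSPA5 was 3.63-fold lower (-1.86 ± 0.075), CALR 2.42-fold (-1.27 ± 0.043) and MANF 2.13-fold (-1.09 ± 0.054). Cholesterol synthesis and uptake genes fell in 20 of 23, rose in 0 and did not pass in 3 (22 lower and 0 higher adjusted over the list alone), with a median of -0.41 (camera adjusted p = 1.1e-11, and adjusted p = 0.015 with an estimated correlation). HMGCS1 (-0.99 ± 0.11), HSD17B7 (-0.84 ± 0.046), INSIG1 (-0.82 ± 0.11) and EBP (-0.64 ± 0.041) fell most, although 2 of the 4 other kept HSD17B7 probes did not pass (0.043 and 0.0066). Of 26 ATF4 and amino acid response genes, 12 fell, 3 rose and 11 did not pass the threshold (14 lower and 3 higher adjusted over the list alone). CHAC1 (-1.09 ± 0.060), ATF4 itself (-0.56 ± 0.042) and PSAT1 (-0.56 ± 0.043) were lower, although another kept CHAC1 probe did not pass (-0.14, adjusted p = 0.12). At a median of -0.16, the camera adjusted p was 0.0079, or adjusted p = 0.15 with an estimated correlation. Of 11 heat shock genes, 7 fell, 1 rose and 3 did not pass the threshold (8 lower and 1 higher adjusted over the list alone). CHORDC1 was at -0.52 ± 0.056 and HSPH1 at -0.48 ± 0.061. The list's median was -0.23, with a camera adjusted p of 0.011 and an adjusted p = 0.15 with an estimated correlation. Over the alternatives the camera adjusted p ranged from 6.0e-04 to 0.060, the last without the dye term. Lysosome genes were the only list shifted up by camera. Of 20, 2 fell, 8 rose and 10 did not pass the threshold (2 lower and 9 higher adjusted over the list alone). PSAP (0.67 ± 0.057), for sphingolipid breakdown, rose, and GLA (-0.55 ± 0.054) and NEU1 (-0.40 ± 0.045) fell. Camera gave an adjusted p of 0.045 at a median of 0.14, and adjusted p = 0.31 with an estimated correlation. That shift was lost in 7 of 25 alternatives (adjusted p from 0.0086 to 0.11), among them those without PP2 replicate 1 (0.057) and replicate 3 (0.11).

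The other lists were not shifted with PP2. Of 24 G1/S and DNA replication genes, 8 fell, 4 rose and 12 did not pass the threshold (8 lower and 6 higher adjusted over the list alone). CDC6 was at -0.36 ± 0.048 (median -0.066, camera adjusted p = 0.16). Of 25 G2/M genes, 2 fell, 9 rose and 14 did not pass the threshold (4 lower and 9 higher adjusted over the list alone). BUB1 was at 0.44 ± 0.046 and AURKB at 0.40 ± 0.047 (median 0.031, camera adjusted p = 0.22). Among 25 MYC target and ribosome biogenesis genes, 7 fell, 4 rose and 14 did not pass the threshold (8 lower and 4 higher adjusted over the list alone). TFRC, the transferrin receptor, was at -0.49 ± 0.051 and WDR43 at -0.38 ± 0.054 (median -0.043, camera adjusted p = 0.25). BCL2 family genes split, with 6 of 16 lower, 3 higher and 7 under the threshold (6 lower and 4 higher adjusted over the list alone, median -0.016, camera adjusted p = 0.60). The survival gene BCL2A1 (-1.06 ± 0.053, and -1.94 by its other kept probe) fell, and the death-promoting genes HRK (0.92 ± 0.079) and BCL2L11 (0.41 ± 0.054) rose, although another kept BCL2L11 probe did not pass (-0.014, adjusted p = 0.92). Of 20 p53 target genes, 8 fell, 6 rose and 6 did not pass the threshold (8 lower and 8 higher adjusted over the list alone). MDM2 was at -1.18 ± 0.045, TP53INP1 at 1.31 ± 0.073 (0.38 by its other kept probe) and SESN1 at 0.96 ± 0.066. Their median was -0.035 and their mean 0.097, and camera gave an adjusted p of 0.91 on the lower side. Of 22 glycolysis and hypoxia genes, 8 fell, 3 rose and 11 did not pass the threshold (8 lower and 4 higher adjusted over the list alone). BNIP3, a mitophagy receptor gene, was at -2.07 ± 0.055 and PFKFB4 at -0.73 ± 0.054 (median -0.036, camera adjusted p = 0.088).

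Interferon-stimulated genes also split with PP2. Of 19, 3 fell, 5 rose and 11 did not pass the threshold (3 lower and 5 higher adjusted over the list alone). OAS1 was at 0.90 ± 0.048 and BST2 at -0.85 ± 0.043 (median 0.0075, camera adjusted p = 0.91). Of 16 FOXO target genes, 3 fell, 6 rose and 7 did not pass the threshold (3 lower and 6 higher adjusted over the list alone). FOXO3 was at 0.73 ± 0.068 (median 0.077, camera adjusted p = 0.22). Of 12 NRF2 target genes, 2 fell, 5 rose and 5 did not pass the threshold (2 lower and 5 higher adjusted over the list alone). NQO1 was at 0.38 ± 0.056 and GCLM at 0.35 ± 0.048 (median 0.12, camera adjusted p = 0.21). Of 8 AHR target genes, 1 fell, 1 rose and 6 did not pass the threshold (1 lower and 1 higher adjusted over the list alone). These were ALDH3A1 (-0.25, chosen after its value was seen) and NQO1. Their median was -0.0013 and their mean 0.013 (camera adjusted p = 0.91 on the lower side). Of 4 complement regulators, too few to test, 1 fell, 0 rose and 3 did not pass the threshold (1 lower and 0 higher adjusted over the list alone). The gene that fell was the complement receptor gene CR2 (-1.43 ± 0.048). Of 10 markers of T, NK and myeloid cells, 4 fell, 0 rose and 6 did not pass the threshold (4 lower and 0 higher adjusted over the list alone). NKG7 was at -0.58 ± 0.054 and CD3D at -0.23 ± 0.049 (median -0.079, camera adjusted p = 0.11). The CD3D call was lost with median centring (adjusted p = 0.31). The 5 markers of fibroblasts and epithelial cells held 1 that fell, COL1A1 (-1.62 ± 0.066), 1 that rose, KRT18 (0.21 ± 0.057), both chosen after their values were seen, and 3 under the threshold (1 lower and 1 higher adjusted over the list alone). Their median was 0.052 and their mean -0.25 (camera adjusted p = 0.91 on the lower side).

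IL4I1 was 8.76-fold lower with dasatinib (-3.13 ± 0.046), C17orf99 5.00-fold (-2.32 ± 0.059) and SERPINA9 4.91-fold (-2.30 ± 0.059). CD180 was 4.79-fold lower (-2.26 ± 0.095) and CD22 4.18-fold (-2.06 ± 0.061). IRAG2 (-1.94 ± 0.057), expressed in germinal-centre cells, and RUNX1T1 (-1.73 ± 0.070), a transcriptional corepressor gene, followed. DAPL1 was 5.72-fold higher (2.52 ± 0.082) by the probe used, and its other kept probe was at 0.92. PDE4B was 4.13-fold higher (2.05 ± 0.042). GPR183, an oxysterol receptor that positions B cells in follicles, was 3.44-fold higher (1.78 ± 0.047) and the orphan receptor tyrosine kinase gene ROR1 3.04-fold (1.61 ± 0.053). Further increases were those of TP53INP1 (1.85 ± 0.073, and 0.53 by its other kept probe), RNF186 (1.49 ± 0.054) and the chaperone gene DNAJB4 (1.44 ± 0.082), and the KCNJ18 probe (2.15 ± 0.048) cannot be told from the near-identical KCNJ12. All of these genes moved the same way on all 4 dasatinib arrays, with a limma adjusted p of at most 1.8e-07. As bounds, LMO2 was at least 1.89-fold lower and ASZ1 at least 1.58-fold lower, while FAM9B was at least 1.94-fold and LINGO1 at least 1.80-fold higher.

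With dasatinib 3857 of 21998 genes (17.5%) passed the threshold, 2019 higher and 1838 lower, and 106 of them changed at least 2-fold, 40 higher and 66 lower. Higher genes were 52.3% of these calls and 90.0% with median centring, which shifts the median of all genes to 0.10 and raises the count to 6246. The count was 1586 without the dye term, 2277 without dasatinib replicate 2 and 2273 without dasatinib replicate 4. Of the 27 lists tested, 9 were shifted, 8 of them down and the FOXO list up, and 0 held with an estimated correlation (fry called 14).

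Of 18 B cell surface and co-receptor genes, 8 fell, 5 rose and 5 did not pass the threshold (9 lower and 6 higher adjusted over the list alone) with dasatinib. CR2 (-1.29 ± 0.048) and FCRLA (-1.28 ± 0.053) fell next to CD180, CD22 and MS4A1. Their median lay at -0.17 (camera adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). Of 21 B cell receptor signalling genes, 11 fell, 3 rose and 7 did not pass the threshold (13 lower and 4 higher adjusted over the list alone). PTPN6 (-1.59 ± 0.055), RASGRP3 (-1.15 ± 0.047) and PIK3AP1 (-1.07 ± 0.10) fell, and PRKCB (0.99 ± 0.068), a protein kinase C gene, rose. At a median of -0.20, the camera adjusted p was 1.7e-04, or adjusted p = 0.067 with an estimated correlation. Among the 10 SRC family kinases and regulators, 4 fell, 2 rose and 4 did not pass the threshold (5 lower and 2 higher adjusted over the list alone). PTPRC (-0.75 ± 0.098), the phosphatase CD45, and PAG1 (-0.73 ± 0.063) were lower. The list's median was -0.18, with a camera adjusted p of 0.011 and an adjusted p = 0.27 with an estimated correlation. Of 21 B cell transcription factor genes, 9 fell, 5 rose and 7 did not pass the threshold (12 lower and 6 higher adjusted over the list alone). BCL6 was at -0.89 ± 0.053, IRF8 at -0.69 ± 0.093 and FOXP1 at 0.68 ± 0.047 (median -0.19, camera adjusted p = 0.066). Another kept FOXP1 probe did not pass (-0.058, adjusted p = 0.50). Plasma cell genes went both ways, with 4 of 14 lower, 4 higher and 6 under the threshold (5 lower and 5 higher adjusted over the list alone). PRDM1, the regulator of plasma cell differentiation, rose (0.88 ± 0.062, and 0.29 by its other kept probe), as did CD27 (0.52 ± 0.045), and TNFRSF17 fell (-1.67 ± 0.090). Their median was 1.0e-04 and their mean -0.039 (camera adjusted p = 0.96 on the upper side). Of 14 MHC class II genes, 8 fell, 0 rose and 6 did not pass the threshold (8 lower and 1 higher adjusted over the list alone). HLA-DOB was at -1.01 ± 0.059 and HLA-DQB1 at -0.53 ± 0.052. Camera gave an adjusted p of 5.2e-05 at a median of -0.15, and adjusted p = 0.22 with an estimated correlation.

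NF-kappaB target genes were also lower with dasatinib. Of 21, 13 fell, 3 rose and 5 did not pass the threshold (14 lower and 4 higher adjusted over the list alone). TRAF1 (-1.31 ± 0.069), EBI3 (-1.31 ± 0.050), LTA (-0.84 ± 0.056) and TNF (-0.83 ± 0.065) fell most. Their median lay at -0.38 (camera adjusted p = 3.7e-06, and adjusted p = 0.099 with an estimated correlation). Of 16 unfolded protein response genes, 11 fell, 1 rose and 4 did not pass the threshold (12 lower and 2 higher adjusted over the list alone). HSPA5 was at -1.03 ± 0.075 and CALR at -0.88 ± 0.043. At a median of -0.31, the camera adjusted p was 9.2e-07, or adjusted p = 0.053 with an estimated correlation. Of 23 cholesterol genes, 10 fell, 0 rose and 13 did not pass the threshold (10 lower and 0 higher adjusted over the list alone). HSD17B7 was at -0.45 ± 0.046 and EBP at -0.37 ± 0.041, a call lost with median centring (adjusted p = 0.064). Of the 4 other kept HSD17B7 probes, 2 did not pass (-0.071 and 0.013). The list's median was -0.14, with a camera adjusted p of 3.6e-05 and an adjusted p = 0.067 with an estimated correlation. Of 26 ATF4 and amino acid response genes, 9 fell, 2 rose and 15 did not pass the threshold (11 lower and 3 higher adjusted over the list alone). CHAC1 was at -0.73 ± 0.060 and SLC7A11 at -0.49 ± 0.061. Another kept CHAC1 probe did not pass (-0.077, adjusted p = 0.49). Camera gave an adjusted p of 0.010 at a median of -0.067, and adjusted p = 0.22 with an estimated correlation. The ATF4 list's adjusted p ranged from 0.0018 to 0.15 over the alternatives, the last with median centring. FOXO target genes rose on balance. Of 16, 1 fell, 9 rose and 6 did not pass the threshold (1 lower and 10 higher adjusted over the list alone). TXNIP (0.86 ± 0.082), the receptor gene IL7R (0.81 ± 0.11) and FOXO3 (0.40 ± 0.068) rose, and BCL6 fell. Another kept FOXO3 probe did not pass (0.15, adjusted p = 0.11). Their median lay at 0.18 (camera adjusted p = 7.4e-04, and adjusted p = 0.099 with an estimated correlation).

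The other lists were not shifted with dasatinib. Of 19 chemokine receptors and adhesion genes, 6 fell, 5 rose and 8 did not pass the threshold (7 lower and 5 higher adjusted over the list alone). GPR183 and CXCR4 (1.36 ± 0.051) rose and ITGB7 (-1.08 ± 0.053) and CD48 (-0.86 ± 0.049) fell. The median was -0.085 and the mean 0.044 (camera adjusted p = 0.77 on the lower side, and fry adjusted p = 0.0068 on the upper). Of 20 immediate early genes, 8 fell, 5 rose and 7 did not pass the threshold (8 lower and 5 higher adjusted over the list alone). CD69, an activation marker, was at 1.22 ± 0.051 (0.66 by its other kept probe) and CCL4 at -0.62 ± 0.056 (median -0.12, camera adjusted p = 0.39). Of 12 ERK feedback and target genes, 2 fell, 1 rose and 9 did not pass the threshold (2 lower and 1 higher adjusted over the list alone). SPRED2 was at -0.65 ± 0.10 (median -0.022, camera adjusted p = 0.51). G1/S and DNA replication genes were lower in 2 of 24, higher in 4 and under the threshold in 18 (2 lower and 5 higher adjusted over the list alone), with MCM5 at 0.30 ± 0.046. Their median of -0.0086 and mean of 0.042 differed in sign (camera adjusted p = 0.67 on the upper side). Of 25 G2/M genes, 2 fell, 4 rose and 19 did not pass the threshold (4 lower and 5 higher adjusted over the list alone). BUB1 was at 0.40 ± 0.046 (median 0.017, camera adjusted p = 0.51). Among 25 MYC target and ribosome biogenesis genes, 0 fell, 2 rose and 23 did not pass the threshold (0 lower and 0 higher adjusted over the list alone). Those that rose were RRP9 (0.15) and CAD (0.21), chosen after their values were seen (median 0.053, camera adjusted p = 0.32). Of 16 BCL2 family genes, 3 fell, 3 rose and 10 did not pass the threshold (5 lower and 3 higher adjusted over the list alone). HRK was at 0.90 ± 0.079 and BCL2A1 at -0.53 ± 0.053, or -1.53 by its other kept probe. The median was -0.015 and the mean 0.024 (camera adjusted p = 0.98 on the upper side). Of 20 p53 target genes, 5 fell, 7 rose and 8 did not pass the threshold (8 lower and 7 higher adjusted over the list alone). GADD45A was at 1.32 ± 0.053 and SESN1 at 0.90 ± 0.066 (median 0.0084, camera adjusted p = 0.35).

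Of 22 glycolysis and hypoxia genes measured with dasatinib, 5 fell, 4 rose and 13 did not pass the threshold (5 lower and 6 higher adjusted over the list alone). BNIP3 was at -1.35 ± 0.055 and PFKFB4 at -0.38 ± 0.054, a call lost with median centring (adjusted p = 0.065). The median was 0.043 and the mean -0.039 (camera adjusted p = 0.77 on the lower side). Of 19 interferon-stimulated genes, 3 fell, 4 rose and 12 did not pass the threshold (4 lower and 5 higher adjusted over the list alone). OAS1 was at 0.77 ± 0.048 and BST2 at -0.56 ± 0.043 (median 0.054, camera adjusted p = 0.77). The BST2 call was lost without the dye term (adjusted p = 0.055). Of 12 NRF2 target genes, 1 fell, 4 rose and 7 did not pass the threshold (1 lower and 5 higher adjusted over the list alone). SLC7A11 fell, and HMOX1, which degrades haem, was at 0.27 ± 0.045 (median 0.066, camera adjusted p = 0.48). Among 8 AHR target genes, 0 fell, 1 rose and 7 did not pass the threshold (0 lower and 0 higher adjusted over the list alone). NQO1 (0.18) was the gene that rose, a call lost in 13 of 25 alternatives (median 0.018, camera adjusted p = 0.98). Of 20 lysosome genes, 2 fell, 4 rose and 14 did not pass the threshold (2 lower and 10 higher adjusted over the list alone). PSAP was at 0.67 ± 0.057 (median 0.12, camera adjusted p = 0.23). Heat shock genes were lower in 1 of 11, higher in 2 and under the threshold in 8 (1 lower and 2 higher adjusted over the list alone, median -0.050, camera adjusted p = 0.79), with DNAJA1 at 0.22 ± 0.044. Of 4 complement regulators, 2 fell, 0 rose and 2 did not pass the threshold (2 lower and 0 higher adjusted over the list alone). The lower genes were CR2 and CD55 (-0.21, chosen after its value was seen). Of 10 markers of T, NK and myeloid cells, 1 fell, 0 rose and 9 did not pass the threshold (1 lower and 0 higher adjusted over the list alone). The lower gene was NKG7 (-0.34, median -0.047, camera adjusted p = 0.15). Of 5 markers of fibroblasts and epithelial cells, 1 fell, 0 rose and 4 did not pass the threshold (1 lower and 0 higher adjusted over the list alone). The lower marker was COL1A1, 2.00-fold lower and chosen after its value was seen. Their median was 0.036 and their mean -0.19 (camera adjusted p = 0.47 on the lower side).

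**Figure D2:**
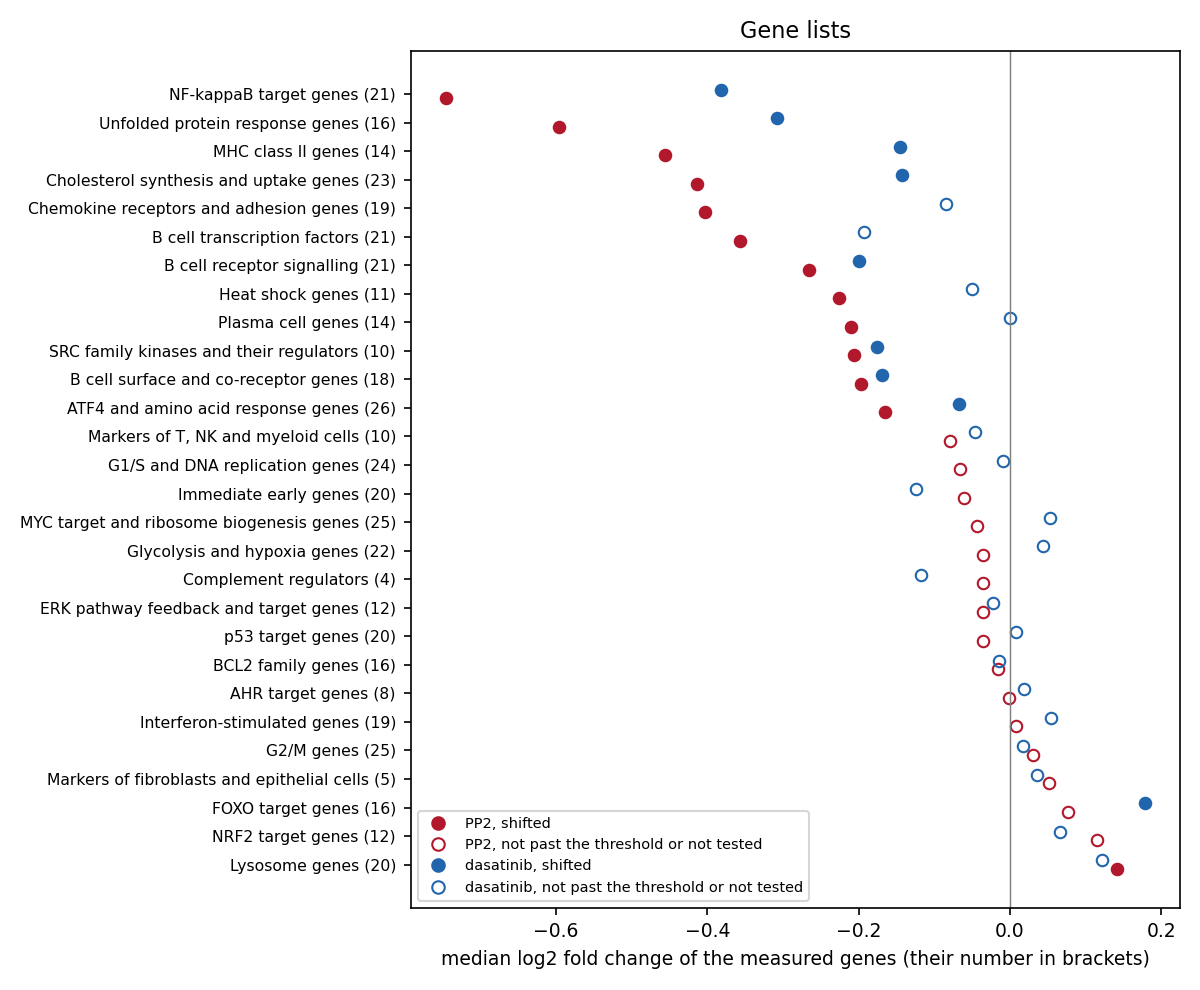
Median log2 fold change of each of the 28 gene lists with PP2 and with dasatinib, with filled symbols for lists shifted by camera and open symbols for lists that did not pass or were not tested. The NF-kappaB list has medians of -0.75 with PP2 and -0.38 with dasatinib, and its shift with dasatinib did not hold with an estimated correlation (adjusted p = 0.099).

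The effects of the compounds were then set against each other, at doses that differ. P4HA2, a collagen prolyl hydroxylase gene, was at -2.18 with PP2 and -0.049 with dasatinib (difference -2.13 ± 0.067, 95% CI -2.27 to -1.98). This rests on 1 probe, and the gene's other kept probe was at -0.069 with PP2 (adjusted p = 0.25) and gave a difference of 0.0083 (adjusted p = 0.96). SGK1 (difference -1.95 ± 0.079), SERPINA9 (-1.85 ± 0.084) and the Fc receptor-like gene FCRL3 (-1.90 ± 0.088) were also lower with PP2, and DAPL1 (-1.90 ± 0.12) was less raised. The other kept probes of FCRL3 and DAPL1 gave smaller differences (-0.68 and -0.69). In the other direction, TSPOAP1 rose with PP2 and was at -0.014 with dasatinib, a difference of 1.45 ± 0.074 (95% CI 1.29 to 1.61). Smaller differences toward PP2 were those of the nuclear noncoding RNA MALAT1 (0.95 ± 0.11), MC1R (0.95 ± 0.085), DHRS2 (0.89 ± 0.060), LAMB2P1 (0.85 ± 0.078) and DRD4 (0.82 ± 0.092). The other kept MALAT1 probes gave smaller differences, from 0.53 to 0.77. CD180 (difference -0.11, 95% CI -0.41 to 0.18, adjusted p = 0.69), CD22 (-0.14, -0.33 to 0.046, adjusted p = 0.36) and PTPN6 (0.058, -0.11 to 0.23, adjusted p = 0.72) fell with both compounds, and their differences did not pass the threshold. The same held for GADD45A, which rose with both (difference 0.088, 95% CI -0.077 to 0.25, adjusted p = 0.55).

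The difference passed the threshold for 2298 of 21998 genes (10.4%), 1068 higher and 1230 lower with PP2 than with dasatinib, and for 52 of them it was at least 2-fold, 3 higher and 49 lower. The higher ones were TSPOAP1 and 2 transcripts with no approved gene symbol. Higher genes were 46.5% of these calls, 17.2% with median centring and 30.5% without the dye term. The count was 1067 with median centring, 1403 with Agilent's log ratio and 669 without the dye term. It was 1503 without PP2 replicate 1, 1346 without PP2 replicate 4, 1499 without dasatinib replicate 2 and 1526 without dasatinib replicate 4.

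NF-kappaB target genes had the lowest camera p of the difference between the compounds. The difference was lower with PP2 for 15 of 21, higher for 0 and under the threshold for 6 (15 lower and 1 higher adjusted over the list alone, median -0.49, camera adjusted p = 1.9e-14, and adjusted p = 0.030 with an estimated correlation), with EBI3 at -1.18 ± 0.071 and RELB at -0.90 ± 0.065. Cholesterol genes were lower with PP2 in 12 of 23 (17 lower and 0 higher adjusted over the list alone, median -0.27, camera adjusted p = 1.6e-09, and adjusted p = 0.030 with an estimated correlation), with HMGCS1 at -0.58 ± 0.15. Chemokine receptors and adhesion genes were lower in 8 of 19 and higher in 1 (9 lower and 1 higher adjusted over the list alone, median -0.26, camera adjusted p = 2.3e-06, and adjusted p = 0.031 with an estimated correlation), with GPR183 at -1.65 ± 0.067. Unfolded protein response genes were lower in 6 of 16 (8 lower and 0 higher adjusted over the list alone, median -0.21, camera adjusted p = 7.3e-06, and adjusted p = 0.030 with an estimated correlation), with HSPA5 at -0.83 ± 0.11. Plasma cell genes were lower in 5 of 14 (6 lower and 1 higher adjusted over the list alone, median -0.18, camera adjusted p = 6.3e-05, and adjusted p = 0.031 with an estimated correlation), with TNFRSF17 at -1.81 ± 0.13 and JCHAIN at -1.69 ± 0.12. PRDM1 was 2.01-fold lower with PP2 than with dasatinib. It rose with dasatinib and did not pass the threshold with PP2 (-0.120, limma adjusted p = 0.158). Its other kept probe gave a smaller difference (-0.304, adjusted p = 0.018). These 5 lists were shifted with an estimated correlation too.

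A further 8 lists were shifted down by camera at its preset correlation and not with an estimated one. They were the MHC class II genes (5 of 14 lower, median -0.20, camera adjusted p = 4.6e-05, and adjusted p = 0.16 with an estimated correlation) and B cell transcription factors (5 of 21 lower, median -0.18, camera adjusted p = 0.0011, and adjusted p = 0.070 with an estimated correlation). They were also the G1/S genes (3 of 24 lower, median -0.10, camera adjusted p = 0.0083, and adjusted p = 0.12 with an estimated correlation) and heat shock genes (3 of 11 lower, median -0.20, camera adjusted p = 0.0083, and adjusted p = 0.14 with an estimated correlation). The same was seen for the glycolysis and hypoxia genes (3 of 22 lower, median -0.091, camera adjusted p = 0.0091, and adjusted p = 0.18 with an estimated correlation) and B cell surface genes (4 of 18 lower, median -0.12, camera adjusted p = 0.012, and adjusted p = 0.18 with an estimated correlation), and for the MYC targets (1 of 25 lower, median -0.099, camera adjusted p = 0.013, and adjusted p = 0.18 with an estimated correlation) and p53 targets (4 of 20 lower and 1 higher, median -0.058, camera adjusted p = 0.027, and adjusted p = 0.26 with an estimated correlation). The B cell surface list lost the shift with scale normalization (adjusted p = 0.17), the heat shock list with the median of a gene's probes (0.057) and the p53 targets without the dye term (0.069). Without PP2 replicate 2, the B cell surface and glycolysis lists (adjusted p = 0.078 each), the MYC targets (0.096) and the p53 targets (0.16) lost the shift. The MYC targets also lost it without dasatinib replicate 1 (0.080) and the p53 targets without dasatinib replicate 2 (0.057) or 4 (0.059). The remaining 14 tested lists did not pass, and among them the median and mean differed in sign for the interferon, AHR and fibroblast lists.

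**Figure D3:**
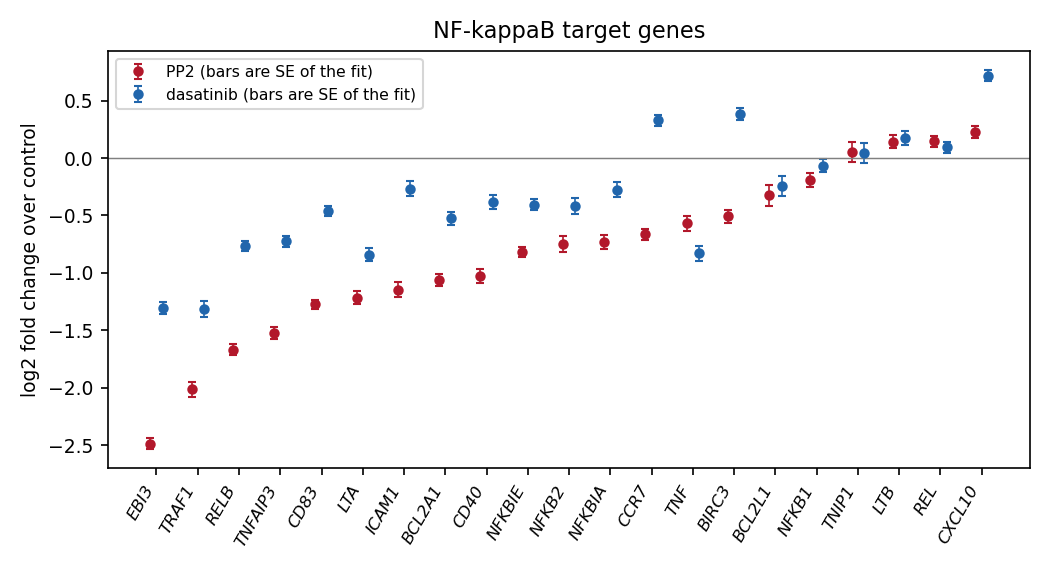
Log2 fold change of the 21 measured NF-kappaB target genes with PP2 and with dasatinib, with bars for the SE of the fit. EBI3 lies at -2.49 with PP2 and -1.31 with dasatinib, and 15 of the genes were lower with PP2 than with dasatinib past the threshold.

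Across the 21998 genes, which are not independent replicates, the effects of PP2 and dasatinib correlated with a Pearson r of 0.73 and a Spearman rho of 0.60. If all control extracts were shared and no gene changed, simulation gives an r of 0.50. The covariance was 0.0383, against 0.0021 simulated for shared controls. That simulation took the controls' spread from the residual between arrays, so a deviation common to all control extracts is not in it. Genes past the threshold in both comparisons numbered 2931, and 95.7% of them moved the same way. Higher in both were 1441, where independent lists would give 391, and lower in both were 1363, where they would give 307. Part of this excess may come from shared controls. Among genes past the threshold in both, the slope of PP2 on dasatinib was 1.17, and of those moving the same way 73.8% changed more with PP2. Opposite calls were fewer, with 34 genes higher with PP2 and lower with dasatinib and 93 the other way. Chosen after their values were seen, these include the surrogate light chain gene VPREB1 (-0.65 with PP2 and 0.89 with dasatinib), the AP-1 family gene BATF (-0.46 and 0.75) and the homing receptor gene CCR7 (-0.66 and 0.33).

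**Figure D4:**
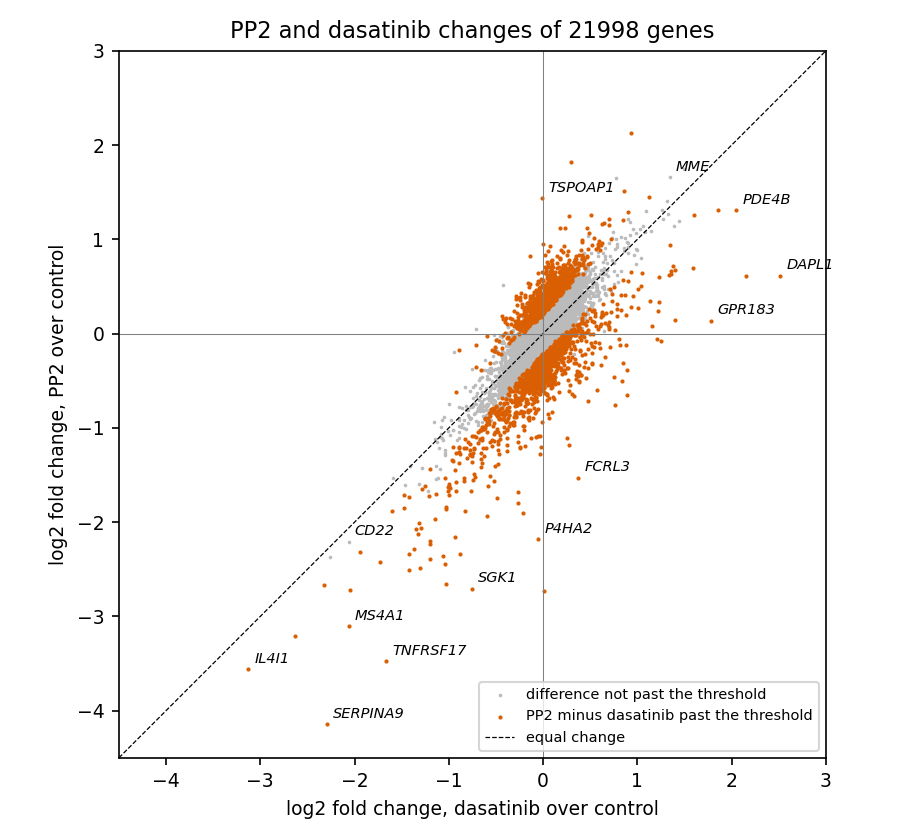
Log2 fold change with PP2 (vertical axis) against that with dasatinib (horizontal axis) for 21998 genes, with genes whose difference passed the threshold in orange and a dashed line of equal change. The changes correlate at r = 0.73, and SGK1 lies below the line at -2.71 with PP2 and -0.75 with dasatinib.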

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

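The tests on NF-kappaB target genes and on MS4A1 were chosen only after the results were seen, and those on dye orientation and on splits of the arrays before. In each compound's group of 4 arrays, a value was picked out when a single array lay far from the other 3 relative to the group's whole range. This happened in 9 of 290 groups tested (3.1%). Chance gives about 1 in 20 for 4 interchangeable values, but the dye effect was left in and sets the orientations apart. The shares can therefore not be compared. FCRLA with PP2 was at -1.51 on replicate 3 and between -1.70 and -1.68 on the others. MANF with PP2 was at -1.29 on replicate 3, against -1.04 to -1.004 on the others. LYN with PP2 was at 0.38 on replicate 3, against 0.26 to 0.27. CD3D with PP2 was at -0.064 on replicate 2, against -0.30 to -0.27. The median of the p53 target genes with PP2 was -0.14 on replicate 2 and between -0.022 and -0.011 on the others. With dasatinib, IRAG2 was at -2.04 on replicate 1, against -1.92 to -1.90, and BCL2L11 was at 0.52 on replicate 1, against 0.38 to 0.39. CD38 was at 0.58 on dasatinib replicate 2 and at 0.44 on the others. The median of the NF-kappaB target genes was -0.20 on dasatinib replicate 4, against -0.42 to -0.41 on the other dasatinib arrays.

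The counts of genes past the threshold were set against other splits of the arrays. Turning the sign of PP2 arrays gives 8 splits, of which 1, the real one, had as many as 7936 genes, and the highest of the others had 0. For dasatinib 1 of 8 splits, the real one, reached 3857 genes, and the highest of the others had 0. In both cases 8 splits are too few for a share under 0.05. For the difference between the compounds, 2 of the 35 splits of the 8 arrays reached the real count of 2298, so chance is not excluded by this count. The other split was that by dye orientation, which gave 5421 genes and was fitted with no dye term, since the term and the split are the same there. All further splits gave 0 genes. A count that high points to a structure of the arrays, their dye orientation, which the dye term removes from the real comparison.

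Arrays of opposite dye orientation correlated less across genes (0.32 to 0.50) than arrays of the same orientation (0.74 to 0.88). A dye effect of the probes and separate cultures behind the orientations are candidate explanations. Over 5024 genes with more than 1 probe, the orientation difference correlated between PP2 and dasatinib arrays at 0.774 for the same probe and at 0.234 between different probes of a gene. The difference of 0.540 (95% bootstrap interval 0.512 to 0.575) is what a probe-specific dye effect predicts, and the 0.234 argues against separate cultures as the whole source. A part from separate cultures stays open, since between-probe r is above 0, and even log2 fold changes correlated between probes only at 0.597 for PP2 and 0.583 for dasatinib.

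NF-kappaB target genes fell further with PP2 than with dasatinib, and a single shared effect that is stronger with PP2 is a candidate explanation. After the dasatinib change was multiplied by the slope of 1.17, the list's median remaining difference was -0.45 (-0.48 to -0.43 on the 4 PP2 arrays, median of all genes 0.0015). Of the 21 genes, 13 stayed lower and 1 higher past the threshold, so multiplying by that slope does not account for the list's values. The list was picked for its low camera p of the difference, so this remainder was largely fixed by values already seen. It is no independent test of a shared effect, and all 4 PP2 arrays were set against the same dasatinib estimate. Each compound had equally many arrays of each dye orientation, so a dye bias of the probes cancels from the difference by design. Over the 24 alternatives of processing, fit and arrays, the list's shift had a camera adjusted p of at most 1.26e-11 at the preset correlation. The shift was thus kept under every normalization tried. In the main setting, the adjusted p with an estimated correlation was 0.030. Some alternatives change neither dye nor normalization, and the list was picked for its low p. The alternatives are therefore no independent test of normalization. The doses differ and each compound was used at a single dose, so a different reach of the doses and different further targets of the compounds stay open and untested.

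MS4A1 fell with both compounds. With 2 arrays of each orientation per compound, a dye bias of the probe cancels from the log2 fold change. Alone, such a bias would also give ratios of opposite sign in the orientations. The highest log2 ratio of MS4A1 on any of the 8 arrays was -1.94. Background correction or normalization would have to lift MS4A1 in some setting, but its highest log2 fold change over the alternatives was -1.87. As a hypothesis, the fall may be a response of the cells to the compounds. That it comes from SRC family kinases, and not from another target that PP2 and dasatinib share, was not tested.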

How the results depend on the processing

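The crossed replicate block below was chosen only after the data were seen. All other alternatives were planned, and the cause of a change was not tested unless it follows from the setting's construction. MS4A1 kept its direction and side of the threshold in all 25 alternatives for each compound, from -3.19 to -2.86 with PP2 and from -2.23 to -1.87 with dasatinib (highest limma adjusted p 1.3e-06 and 2.1e-05). The correlation of the effects ran from 0.66 with Agilent's log ratio to 0.73. Requiring a 2-fold change, which by construction keeps fewer genes, left 226 with PP2, 106 with dasatinib and 52 for the difference. Without the dye term the counts were 4811, 1586 and 669. Median centring gave 6246 genes with dasatinib and 1067 for the difference, and Agilent's log ratio and the deposited value table each gave 1403 for the difference. Leaving out each array in turn gave 6111 to 8108 genes with PP2, 2273 to 4218 with dasatinib and 1346 to 2382 for the difference, and -3.19 to -2.98 and -2.16 to -1.97 for MS4A1. The dasatinib count was 2277 without dasatinib replicate 2 and 2273 without replicate 4. That of the difference was 1503 and 1346 without PP2 replicates 1 and 4, and 1499 and 1526 without dasatinib replicates 2 and 4. The PP2 lists shifted were 3 with an estimated correlation and 24 with fry, which does not compare a list with other genes, and 13 without any one array. The dasatinib lists were 0 and 14, and 9 to 10 without any one array. No shifted list turned its direction. Of the others, the chemokine receptor and adhesion list with dasatinib lay on the lower side with camera and was called on the upper side with fry (adjusted p = 0.0068). With the replicate block, the counts were 7647, 3594 and 2012, and the lists 13 and 9. Whether arrays with the same number share more than the number is not known. Forward arrays of the compounds with the same number deviated with r = -0.10 across genes. Between the compounds, swap arrays gave -0.46, PP2 forward against dasatinib swap arrays -0.34, and PP2 swap against dasatinib forward arrays 0.096. Within a compound, forward against swap arrays gave 0.32 for PP2 and 0.024 for dasatinib. Whether swaps repeat the RNA of replicates 1 and 2 stays open. With swap pairs averaged, the counts for PP2, dasatinib and the difference were 7311, 3152 and 1626 in label order and 8933, 4872 and 3070 in the other pairing. The replicate block with the numbers of the dasatinib forward arrays crossed, in which no swaps were averaged, gave 7914, 3846 and 2193. Of values of named genes over the alternatives, 2866 of 2895 with PP2, 2534 of 2645 with dasatinib and 460 of 480 for the difference kept direction and side. Reversed values were those of genes near 0. BLK with PP2 was -0.052 without PP2 replicate 3 (-0.052 to 0.067 over the arrays left out), and LYN with dasatinib was 0.13 with median centring. The difference of SRC was 0.036 with Agilent's log ratio and the value table, 0.012 with scale normalization, 0.011 without PP2 replicate 3, and 0.010 and 0.013 without dasatinib replicates 1 and 3 (-0.031 to 0.013 over the arrays left out). Leaving out saturated probes removed nothing and says nothing about stability. Signal over background limits the fold of dim probes, which are given as bounds.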

Other observations

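The genes and families here were chosen after their values were seen. Most measured members of the metallothionein gene family, whose proteins bind zinc and copper, rose with PP2. Of 9 measured, 7 were higher and 2 did not pass the threshold, with a median of 0.53, and as many were higher with median centring, scale normalization and Agilent's log ratio. MT1L (0.71 ± 0.048), MT1B (0.71 ± 0.045), MT1E (0.67 ± 0.050) and MT2A (0.64 ± 0.054) rose most, but their probes can read near-identical copies, so the genes are not independent. The counts rest on the probe used for each gene. MT1X was at 0.41 with PP2, but its other kept probe fell with PP2 (-0.32, limma adjusted p = 0.0052) and dasatinib (-0.27, adjusted p = 0.026). With PP2, the other kept probe of MT1H was at 0.017 (adjusted p = 0.81) and that of MT1E at 0.19 (adjusted p = 0.022). With dasatinib 0 of 9 passed (limma adjusted p, median 0.034), although 5 were higher with median centring (median 0.22). The difference between the compounds passed for 7 genes, and for 5 with median centring. Fc receptor-like genes were lower in 7 of 8 with PP2, and as many were in each of those scalings. By their other kept probes, FCRL1 fell with PP2 (-0.23, limma adjusted p = 0.0040) and FCRLB did not pass (-0.17, adjusted p = 0.11). With dasatinib 5 were lower and 1 higher, or 4 lower and 1 higher with median centring. FCRL2 fell with both (-1.40 with PP2, -0.51 with dasatinib), and FCRL3 moved in opposite directions (-1.53, 0.37, and -0.50, 0.18 by its other kept probe). The size of change of FCRL4 and FCRL5 is not given, since the probes used were not well above background on all treated channels. Replication-dependent histone genes were lower in 30 of 60 with dasatinib (median -0.19), but in 2 with median centring, 6 with Agilent's log ratio and 37 with scale normalization. With PP2, 6 were lower and 4 higher (median -0.037, or 0.019 with median centring).

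Among single genes, IL21R was 3.31-fold lower with PP2 and 2.32-fold with dasatinib, and the Toll-like receptor gene TLR10 3.32-fold and 2.69-fold. The cytokine genes IL10 (-1.44 and -0.94) and CCL17 (-1.01 and -0.63) were also lower. LAPTM5, a lysosomal negative regulator of the B cell receptor, fell 5.04-fold and 2.67-fold. Larger with PP2 was the fall of CYBB, the phagocyte oxidase subunit (-1.68 and -0.27, difference -1.41 ± 0.072). Raised with dasatinib past the threshold, and not with PP2, were SMAD1 (1.25 against -0.083, difference -1.34 ± 0.093) and the oncogene TCL1A (0.80 against -0.053, difference -0.85 ± 0.072). The glucocorticoid-induced gene TSC22D3 rose with both (1.08 and 1.15).

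Genes called in opposite directions include MAL (-0.60 with PP2, 0.57 with dasatinib), BIRC3 (-0.51, 0.38) and UBD (-0.40, 0.38), and their differences passed the threshold (-1.17 ± 0.071, -0.89 ± 0.078 and -0.78 ± 0.071). BIRC3 and CCR7 are members of the NF-kappaB list that rose with dasatinib, as did CXCL10 (0.72), while most measured members fell.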
